A study of Mus musculus with 6 samples.

How the data were processed

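RNA sequencing was done on B16F10 cells, an established mouse melanoma line, in 6 libraries: 3 from cells given rPPAA18C6@Dox at 50 μg/mL and 3 from cells given PBS, all collected after 8 h. The labels name the preparation only by this code, and the series title describes a potassium ionophore-based nanoplatform that responds to reactive oxygen species. Per the labels' protocols, total RNA was made into libraries with a stranded poly(A) mRNA kit. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

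The deposited table gives 1 value per gene and library for 15726 genes, with a p-value for each gene. The deposited values were read as FPKM, that is, the reads of each gene divided by its length and by the depth of the library. The header does not name this unit, and it was inferred from the values: the columns sum to between 385203 and 392470, and the values of a gene stand in ratios of whole numbers. The genome build is mm9, per the submitters' processing notes. The aligner, the counter, the use of strand and any filter on low values are not given in the sources used here. Many symbols of the table are those of later mouse annotations, so no gene coordinates are given. The deposited p-value column is the authors' own comparison, with the test not stated in the file header. Columns named for PBS with a number matched the titles of the PBS libraries. The other 3 columns carry a letter that the titles do not hold, and were assigned to the rPPAA18C6@Dox libraries by elimination and by their number, so the sign of every difference rests on this reading.

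Depth was worked out from the steps in the FPKM values. For 15724 of the 15726 genes, 1 factor per gene turned all 6 deposited values into whole reads within a tolerance of 0.01. The recovered totals were 36594469, 36740725 and 36629229 reads for the rPPAA18C6@Dox libraries and 37067116, 36775201 and 36380461 reads for the PBS libraries. The gene lengths that these factors imply had a Spearman correlation of 0.758 across 14079 genes with the longest GENCODE vM21 transcript, and a median ratio to it of 1.06 (genes are not independent replicates). Libraries of the same group differed by more than sampling noise: the mean chi-square per gene of the 6 pairs was between 2.38 and 3.98, where noise alone gives 1, so each library was counted separately. Between groups the range was 8.49 to 11.4.

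Because the values are not counts, the main test was limma 3.58.1 in R 4.3.3 with a mean-variance trend on log2(FPKM + 1), two-sided and unpaired, with Benjamini-Hochberg adjustment and a threshold of 0.05. A gene was tested if its mean reached 1 FPKM in either group, which left 10680 genes and put 5046 aside. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with few reads. The design fixed before the data were examined gave a count model for a table of counts and this test for a normalized unit. On simulated libraries with 10631 tested genes, drawn from the recovered reads of these libraries, the test found 0% of 50 genes changed 1.1-fold, 80% of 50 changed 1.25-fold, 100% of 50 changed 1.5-fold and 98% of 50 changed 2-fold. Of its 153 calls, 13 (8.50%) were false, above the nominal 5%. On the same simulated libraries limma's voom, used below as an alternative, made 154 calls, of which 6 were false. The simulation gave all genes the same dispersion (0.00205) and changed few of them, which makes the adjusted threshold stricter than with the 1060 calls made here. Its shares therefore do not set a lower limit on the changes found: the smallest call here was 0.079 on the log2 scale.

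The gene lists, 24 in all, were fixed before the data were examined, from the series title, a reading of Dox in the code name as a drug that damages DNA, the cell line, RNA quality and other cell types. Each was tested with camera in limma at a preset correlation of 0.01 between genes and adjusted over all lists, and again with a correlation estimated per list. The estimated form also takes its p from the few residual degrees of freedom of the 6 libraries, which by itself makes it stricter. The fry test, adjusted over the lists, was run beside camera. Its directional form asks whether a list moves on balance one way, and its mixed form whether members change in either direction. Neither compares a list with other genes. List members were matched by symbol, then by synonym. A list member with no row in the table was not analysed here. The genes named were the 6 largest rises and 6 largest falls past the threshold with a mean of at least 5 FPKM, no overlap between groups and no predicted or clone name, 10 genes fixed in advance, and the 2 members of each list with the smallest p, to which the next 2 were added for 4 lists. Slc24a4 and Mdm2 were added after their values were seen. Some genes that the rule names are not reported here.

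The alternatives fixed before the data were examined were limma without the trend, quantile normalization, no filter, a mean of at least 5 FPKM, a pseudocount of 0.1, a block for the replicate number, a test against a 1.5-fold threshold, and each library left out in turn. After the data were seen, limma's voom was added on the recovered reads scaled by median ratios, with the same genes or with a mean of at least 10 reads. Alternatives meant for a table of counts were not run. Exons of 17 of the 71 named genes that the table lists overlap exons of another listed gene in GENCODE vM21. Reads of such pairs may be mixed, depending on how the authors counted. They are named beside the values, except for ATP8, Cryab, Ctsb, Kcnj13, Kif20a, Pdia3, Plk3, Txnip and Usp18.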

Results

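B16F10 mouse melanoma cells were compared 8 h after addition of rPPAA18C6@Dox at 50 μg/mL (3 libraries) or PBS (3 libraries) by poly(A) RNA sequencing. The recovered depth was 36380461 to 37067116 reads per library, and the 10 genes with the most reads took 5.96% to 6.27% of them. Values are FPKM, given as mean ± SD with n = 3 libraries per group, and fold changes are limma estimates on the log2(FPKM + 1) scale with their standard error (SE). The comparison asks how the cells' gene expression responded to the preparation, and the series title names ER stress and pyroptosis as the processes of interest.

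Most tested genes of the melanocyte programme and of protein folding in the endoplasmic reticulum (ER) were higher in cells given rPPAA18C6@Dox, and some of those of DNA replication and mitosis were lower. Of the 20 tested melanocyte genes 15 rose and none fell, and of the 27 tested ER chaperone and unfolded protein response genes 16 rose and none fell. None of the 28 mitotic genes rose and 13 fell, and none of the 28 DNA replication genes rose and 12 fell. With the correlation between genes estimated, the melanocyte list stayed past camera's threshold and the ER, mitotic and replication lists did not (adjusted p = 0.0733, 0.0733 and 0.116). That form of camera is also stricter because it uses few degrees of freedom. Most of these changes were small: the median member was 17.9% higher in the melanocyte list, 9.75% higher in the ER list, and lower by 0.10 on the log2 scale in both cell cycle lists. No tested pyroptosis gene rose, and the p53 target Cdkn1a did not pass the test.

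Across all 10680 tested genes, 1060 changed at an adjusted p under 0.05 (limma, Benjamini-Hochberg), 498 higher and 562 lower. With 1 library left out the count was 600 to 749, with 314 to 371 higher and 285 to 381 lower, and with no filter on low values it was 681. Which side had more genes depended on the method: quantile normalization gave 551 higher and 499 lower, and voom 843 higher and 706 lower. The median size of the change among them was 0.18 on the log2 scale, and 235 changed at least 1.2-fold. In 1346 tested genes every rPPAA18C6@Dox library lay above every PBS library and in 1995 every one lay below. Together these were 31.3% of the tested genes, where the average over all equal divisions of the 6 libraries is 10%. Genes share the same libraries, so a single division can depart from that average by chance. Only Slc24a4, a sodium, calcium and potassium exchanger, passed a fitted 2-fold change. It rose from 0.512 ± 0.156 to 3.23 ± 0.260 FPKM (log2 fold change 1.49, SE 0.0822, adjusted p = 8.40e-06), a ratio of means of 6.31, and was named after its values were seen. The count of such genes depended on the scale: 6 with a pseudocount of 0.1 and 11 with voom on the recovered reads.

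The largest rise among genes with at least 5 FPKM was that of Ppargc1a, a coactivator that drives mitochondrial biogenesis, from 4.56 ± 0.188 to 9.98 ± 0.280 FPKM (log2 fold change 0.98, SE 0.0419, adjusted p = 1.84e-06). Eps8, an actin regulator downstream of the epidermal growth factor receptor, rose from 63.9 ± 0.315 to 121 ± 2.45 FPKM (0.91, SE 0.0241). Met, the receptor of hepatocyte growth factor, rose from 9.55 ± 0.288 to 18.9 ± 0.740 FPKM (0.91, SE 0.0384). Deptor, an inhibitor of mTOR, rose by a log2 fold change of 0.78, Ano3, of the anoctamin family, by 0.77 and the hyaluronidase Hyal1 by 0.68. Hyal1 overlaps exons of Hyal3 and Naa80 on the same strand. Ano3 overlaps Muc15 and Deptor overlaps Gm9920, both on the other strand, and reads of all these pairs may be mixed. Slc24a4, Ppargc1a, Eps8 and Met were also the 4 genes that passed a test against a 1.5-fold threshold.

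**Figure D1:**
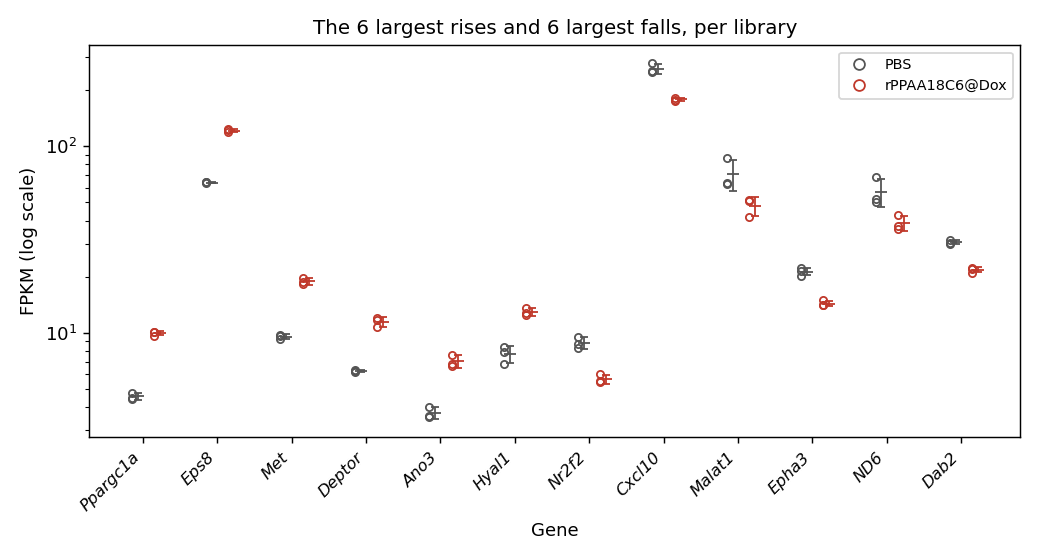
FPKM of each library (circles) on a log scale for the 6 largest rises and 6 largest falls, with PBS in grey and rPPAA18C6@Dox in red. Dashes and bars give the mean and SD of 3 libraries, and the groups do not overlap for any of the 12 genes, a condition of their choice.

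Among the falls, Nr2f2, an orphan nuclear receptor, went from 8.85 ± 0.651 to 5.65 ± 0.314 FPKM (log2 fold change -0.57, SE 0.0552, adjusted p = 0.000200). The interferon-induced chemokine Cxcl10 went from 260 ± 16.4 to 178 ± 3.66 FPKM (-0.54, SE 0.0399, adjusted p = 3.48e-05). The nuclear noncoding RNA Malat1 (-0.54, SE 0.115), the ephrin receptor Epha3 (-0.54, SE 0.0403), the mitochondrially encoded ND6 (-0.54, SE 0.0996) and the endocytic adaptor Dab2 (-0.47, SE 0.0323) also fell. PBS replicate 1 was the highest library for both Malat1 (86.1 FPKM) and ND6 (68.2 FPKM), and without it their log2 fold changes were -0.39 and -0.40. The call for Malat1 was lost without rPPAA18C6@Dox replicate 3 (adjusted p = 0.0655), and with no filter on low values Malat1 and ND6 both lost theirs (0.0884 and 0.0610). ND6 overlaps ND5, Cxcl10 overlaps Art3 and Nr2f2 overlaps B130024G19Rik, each on the other strand.

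In the melanocyte list the members with the smallest p were Met, Cdk2, the melastatin channel Trpm1 and the melanin enzyme Tyrp1. Trpm1 rose from 13.3 ± 0.213 to 18.7 ± 0.320 FPKM (log2 fold change 0.45, SE 0.0309) and Tyrp1 from 1767 ± 10.5 to 2167 ± 23.6 FPKM (0.29, SE 0.0218). Cdk2 (0.39, SE 0.0226) shares exon sequence on the other strand with the melanosome gene Pmel, so its reads may in part be those of Pmel. All 20 tested members had a positive estimate, and 18 rose when adjusted over the list alone. The list was higher than other genes (camera adjusted p = 1.05e-23), and it was the only list past the threshold with an estimated correlation (adjusted p = 0.0347). The directional fry test gave an adjusted p of 6.00e-05.

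ER chaperones that rose included Hspa5 (BiP), from 361 ± 14.7 to 415 ± 1.55 FPKM (log2 fold change 0.20, SE 0.0293, adjusted p = 0.00269), Dnajc3 (0.30, SE 0.0265), Manf (0.27, SE 0.0273), calreticulin (Calr, 0.19, SE 0.0214) and Pdia4 (0.20, SE 0.0240). All 27 tested members had a positive estimate and 19 rose when adjusted over the list alone (camera adjusted p = 1.89e-15). The adjusted p was 0.0733 with an estimated correlation, and the directional fry test gave 0.00162. Manf overlaps exons of Rbm15b on the same strand and of Dcaf1 on the other strand. Among targets of ATF4 and CHOP, transcription factors of the stress response, 4 of 25 rose and 1 fell, the same counts as when adjusted over the list alone. Atf3 rose from 5.91 ± 0.804 to 9.35 ± 1.49 FPKM (0.58, SE 0.104), Ddit3, which encodes CHOP, from 17.8 ± 1.49 to 22.2 ± 2.20 FPKM (0.30, SE 0.0723) and Sars by 0.13 (SE 0.0297). Atf4 itself was at 190 ± 4.70 and 198 ± 8.67 FPKM (0.06, SE 0.0333, adjusted p = 0.309). As a list they missed the threshold (camera adjusted p = 0.0536), and the adjusted p was 0.668 with an estimated correlation. They were past it with no filter (0.0494), with voom (0.0295) and in 4 of the 6 leave-one-out fits (range over the fits 0.0108 to 0.298). Single libraries decided 2 of these calls: Ddit3 was lost without rPPAA18C6@Dox replicate 1 or 3 or PBS replicate 1 or 2 (adjusted p up to 0.0987), and Sars without any 1 of the PBS libraries (up to 0.0685). With no filter on low values the calls of Atf3 (0.0524), Ddit3 (0.104) and Sars were all lost, and without the trend those of Ddit3 (0.0656) and Sars (0.0616).

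In the cell cycle lists, the mitotic kinesin Kif20a fell by 0.19 on the log2 scale (SE 0.0253) and the kinase Aurkb by 0.17 (SE 0.0229). Of the DNA replication genes, Uhrf1, which maintains DNA methylation, fell by 0.19 (SE 0.0264) and the ribonucleotide reductase subunit Rrm2 by 0.14 (SE 0.0244). Adjusted over the list alone, 18 mitotic and 18 replication genes fell. Both lists were lower than other genes (camera adjusted p = 3.30e-10 and 3.18e-09). The adjusted p was 0.0733 and 0.116 with an estimated correlation, and fry gave 0.00111 and 0.00424.

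Genes of the lysosome and autophagy list rose in 7 of 27 cases and fell in none, with the protease Ctsb (log2 fold change 0.22, SE 0.0235), the proton pump subunit Atp6v1b2 (0.17, SE 0.0269), the sialidase Neu1 (0.21, SE 0.0386) and the galactosidase Gla (0.30, SE 0.0594) leading by p. Adjusted over the list alone, 9 rose and 1 fell. The camera adjusted p was 6.31e-05, and the adjusted p was 0.0733 with an estimated correlation. The call for Gla was lost without PBS replicate 1 (adjusted p = 0.0507). Immediate early genes went both ways, with 7 of 21 higher and 2 lower, or 10 and 3 adjusted over the list alone. Fos went from 1.79 ± 0.204 to 3.48 ± 0.165 FPKM (0.68, SE 0.0631) and the phosphatase gene Dusp4 rose by 0.52 (SE 0.0303), whereas its relative Dusp6 fell by 0.40 (SE 0.0326) and Myc by 0.30 (SE 0.0387). The camera adjusted p was 0.0247, and the adjusted p was 0.490 with an estimated correlation. It was 0.110 without rPPAA18C6@Dox replicate 3 and 0.485 with a mean of at least 5 FPKM.

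**Figure D2:**
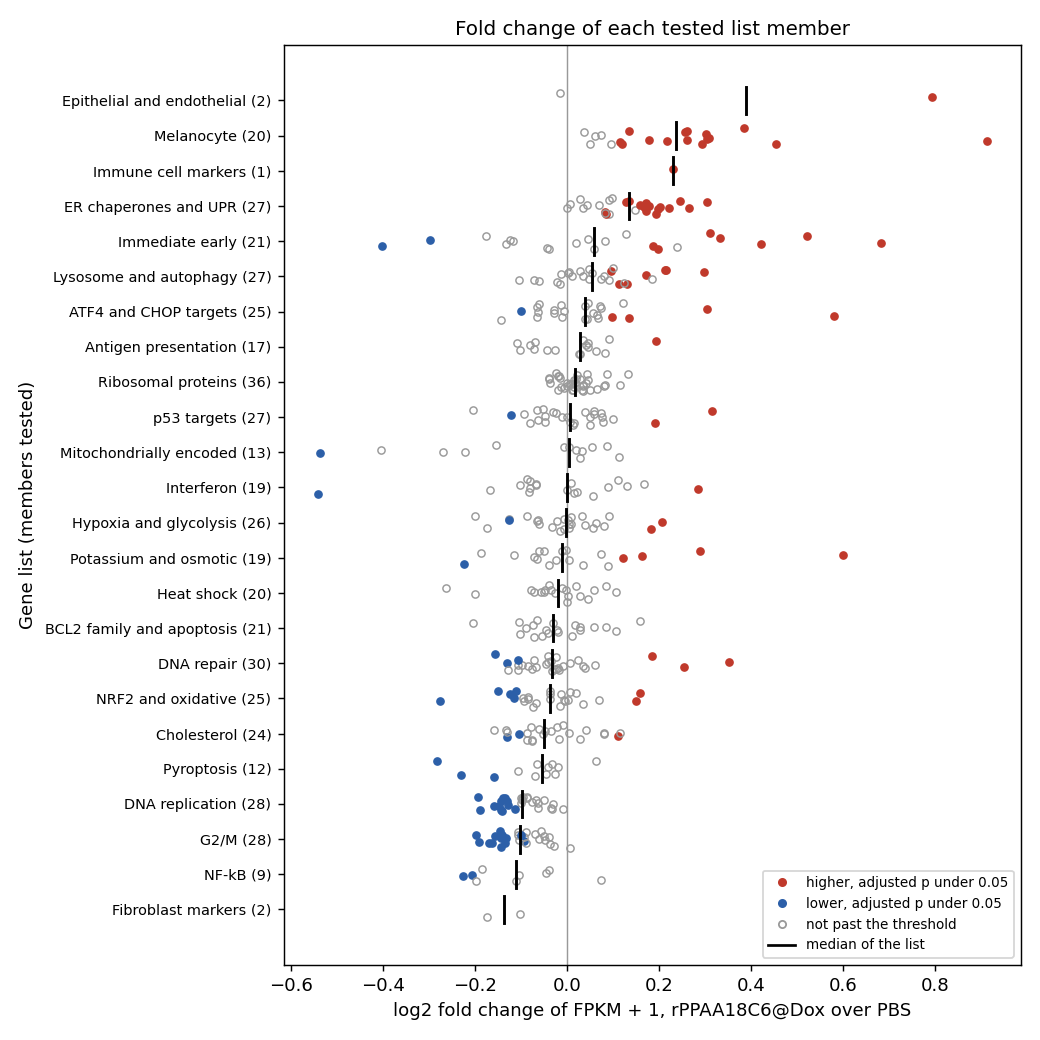
Log2 fold change of FPKM + 1 (rPPAA18C6@Dox over PBS, horizontal axis) of every tested member of the 24 lists (rows, ordered by median). Filled points passed an adjusted p of 0.05, open points did not, and black bars are list medians, 0.24 for the melanocyte list and -0.10 for the mitotic list.

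Among pyroptosis genes 3 of 12 fell and none rose, over all genes or adjusted over the list alone. The gasdermin Gsdmc went from 53.01 ± 0.883 to 45.1 ± 1.95 FPKM (log2 fold change -0.23, SE 0.0333), Txnip from 26.3 ± 1.24 to 23.4 ± 0.491 FPKM (-0.16, SE 0.0367) and Gsdmd, the pore-forming target of inflammatory caspases, from 1.14 ± 0.0337 to 0.766 ± 0.131 FPKM (-0.28, SE 0.0710, adjusted p = 0.0344), with 46 to 85 recovered reads per library. The gasdermin Gsdme was below the filter at 0.579 ± 0.0251 and 0.597 ± 0.0345 FPKM. Casp1 and Nlrp3 were not analysed here. The list had a camera adjusted p of 0.0345, and the adjusted p was 0.214 with an estimated correlation, 0.0914 with no filter and 0.0518 with a mean of at least 5 FPKM. It stayed past camera's threshold with voom (0.0311) and in every leave-one-out fit (0.0253 to 0.0493), and directional fry gave 0.00505. The Gsdmd call was lost in every leave-one-out fit but that without rPPAA18C6@Dox replicate 1 (adjusted p up to 0.104), and the Txnip call without rPPAA18C6@Dox replicate 2 or 3 or PBS replicate 3 (up to 0.0793). Gsdmd was also lost with no filter, with the replicate block and with voom at a mean of at least 10 reads, and Txnip with no filter and without the trend. Values of mRNA say nothing about the cleavage of gasdermins.

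Targets of p53, which drugs that damage DNA induce, were 2 higher and 1 lower of 27, or 3 and 2 adjusted over the list alone (camera adjusted p = 0.542). Cdkn1a, the p21 inhibitor, was at 157 ± 0.722 and 158 ± 5.64 FPKM (log2 fold change 0.01, SE 0.0279, adjusted p = 0.900; the sign turns with quantile normalization), and the p53 regulator Mdm2 at 18.8 ± 0.463 and 18.6 ± 0.178 FPKM (-0.01, SE 0.0305, adjusted p = 0.850; the sign turns with voom). Phlda3 (0.19, SE 0.0243) and Plk3 (0.31, SE 0.0650) rose, the latter not without rPPAA18C6@Dox replicate 3 or PBS replicate 2 (adjusted p up to 0.0551). Of 30 DNA repair genes, 3 rose and 3 fell, with Brca1 (0.35, SE 0.0323) and Xrcc5 (0.19, SE 0.0240) leading (camera adjusted p = 0.572), and the counts were the same adjusted over the list alone. In the BCL2 family and apoptosis list 0 of 21 members passed limma's threshold, 4 had an unadjusted p under 0.05 and voom called 3 (camera adjusted p = 0.803). Apaf1 (0.11, adjusted p = 0.0512) and Bbc3 (-0.20, adjusted p = 0.0552) had the smallest p. None of these 3 lists passed the threshold with an estimated correlation.

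Of 25 NRF2 and oxidative stress genes 2 rose and 5 fell, or 2 and 6 adjusted over the list alone. As a list they missed camera's threshold (adjusted p = 0.115) but were past it with quantile normalization (0.0471). Osgin1 fell by 0.28 (SE 0.0345), Gsta4 rose by 0.15 (SE 0.0233), and Hmox1, the haem-degrading enzyme, was at 45.8 ± 1.80 and 48.2 ± 2.58 FPKM (log2 fold change 0.07, SE 0.0412, adjusted p = 0.316). For heat shock, 0 of 20 genes passed in limma, 6 had an unadjusted p under 0.05 and voom called 4 (camera adjusted p = 0.803), with Cryab (0.09, adjusted p = 0.0517) and Hspb1 (-0.20, adjusted p = 0.0519) leading. Of 19 potassium transport and osmotic genes 4 rose and 1 fell, or 4 and 3 adjusted over the list alone (camera adjusted p = 0.542). The channel Kcnj13 went from 0.771 ± 0.0898 to 1.68 ± 0.133 FPKM (0.60, SE 0.0675), and the taurine transporter Slc6a6 fell by 0.22 (SE 0.0278).

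Of 19 interferon genes 1 fell, Cxcl10, and 1 rose, Usp18 (log2 fold change 0.29, SE 0.0570), or 2 and 3 adjusted over the list alone (camera adjusted p = 0.930). Of 9 NF-κB genes 2 fell, Nfkb1 (-0.21, SE 0.0362) and Csf1 (-0.23, SE 0.0544), also adjusted over the list alone. The NF-κB list missed camera's threshold (adjusted p = 0.0579) but was past it with the replicate block (0.0333) and in 2 of the leave-one-out fits, and directional fry gave 0.00548. The Csf1 call was lost without rPPAA18C6@Dox replicate 2 or 3 or PBS replicate 1 or 2 (adjusted p up to 0.0975). In antigen presentation 1 of 17 genes rose, Calr, which the ER list also holds, as it does the next gene Pdia3 (0.09, adjusted p = 0.0665). The list gave a camera adjusted p of 0.280 and the same count adjusted over the list alone. Cholesterol genes had 1 rise and 2 falls of 24, or 2 and 7 adjusted over the list alone (camera adjusted p = 0.211). The list's direction was down, with 7 estimates above 0, so Dhcr7 (0.11, SE 0.0281), the 1 rise, goes against it. In hypoxia and glycolysis 2 of 26 rose and 1 fell, or 2 and 2 adjusted over the list alone (camera adjusted p = 0.807), led by Eno1 (-0.13, SE 0.0257) and Hk2 (0.18, SE 0.0435). The calls of Dhcr7, Eno1 and Hk2 were each lost in at least 4 of the 6 leave-one-out fits, with adjusted p up to 0.107, 0.0561 and 0.0891.

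Among 36 ribosomal protein genes 0 passed in limma, 6 had an unadjusted p under 0.05 and voom called 6. Rpl27 (log2 fold change 0.13, adjusted p = 0.0699) and Rps23 (0.08, adjusted p = 0.10) led. The camera adjusted p was 0.0413, the adjusted p was 0.766 with an estimated correlation, and it was 0.537 with quantile normalization, 0.0526 with a mean of at least 5 FPKM and up to 0.782 with 1 library left out. Of the 13 mitochondrially encoded genes only ND6 passed, also adjusted over the list alone, and ATP8 (-0.40, adjusted p = 0.188) came next (camera adjusted p = 0.930). ATP8, with 18 to 48 recovered reads per library, passed limma with the replicate block (adjusted p = 0.00684). Few markers of other cell types reached the filter: Cd68 of 16 immune markers, at 1.27 ± 0.0623 and 1.66 ± 0.0551 FPKM (0.23, adjusted p = 0.0311), Col1a2 (-0.17, adjusted p = 0.163) and Pdgfrb (-0.10, adjusted p = 0.312) of 12 fibroblast markers, and Vwf, at 1.497 ± 0.175 and 3.32 ± 0.141 FPKM (0.79, SE 0.0635, adjusted p = 5.91e-05), and Pecam1 (-0.01, adjusted p = 0.920, the sign turns with quantile normalization) of 14 epithelial and endothelial markers. These 3 lists missed camera's threshold (adjusted p = 0.114, 0.280 and 0.0591) but passed directional fry (0.00469, 0.0378 and 0.00424). With so few tested members these are hardly tests of a list, and the immune result is that of Cd68 alone. Mixed fry did not call the fibroblast (0.423) or the epithelial and endothelial list (0.128). The epithelial and endothelial list was past camera's threshold with voom (0.0149), with no filter (0.0381) and in 2 of the leave-one-out fits. The Cd68 call was lost in each of the 6 leave-one-out fits (adjusted p up to 0.0952), and with the replicate block and both voom fits (up to 0.241).

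With the preset correlation, 8 of the 24 lists passed camera's threshold, and with an estimated correlation 1 did. Directional fry called 11 lists and mixed fry 19. Other divisions of the 6 libraries into 3 and 3 also gave up to 8 lists at the preset correlation, so that count alone does not set the real division apart. These divisions are not a reference without change. Each puts unequal numbers of rPPAA18C6@Dox libraries on its sides, so part of a real difference stays. The melanocyte and ER lists passed in all 9 of the other divisions, each time higher on the side with more rPPAA18C6@Dox libraries. The mitotic list passed in 7, the replication list in 6 and the pyroptosis list in none. The ribosomal protein list also passed in 7, but not always in its real direction. It was lower on the sides with rPPAA18C6@Dox replicates 1 and 2 and a PBS library (camera adjusted p = 0.0146, 0.00753 and 0.00314). Those passes are not the rest of a treatment difference. In the interferon list and the hypoxia and glycolysis list the median and mean were below 0 while camera gave the direction as up. The potassium list had a median below 0 and a mean above it, and the mitochondrially encoded list the reverse. No group was given a part of the preparation alone. The authors' deposited table gives a p-value under 0.05 for 2749 genes, and 860 of the 1060 genes called here also pass 0.05 after Benjamini-Hochberg adjustment of those p-values.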

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

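Voom on the recovered reads was the one kind of alternative chosen after the data were seen. No alternative turned the direction of any of the 55 named genes that passed the test, and 41 of them passed under every alternative that tested them. Of the rest, 12 were lost with no filter on low values (Atf3, Csf1, Ddit3, Eno1, Gla, Gsdmd, Hk2, Malat1, ND6, Plk3, Sars and Txnip), 6 without the trend, 3 with the replicate block, 1 or 2 with voom and between 4 and 9 with 1 library left out. Those lost with the replicate block were Cd68, Dhcr7 and Gsdmd, and that fit gained ATP8. The count of 1060 changed genes was 681 with no filter, where more genes are tested, and 600 to 749 with 1 library left out, where fewer samples enter. Higher and lower genes were 843 and 706 with voom, or 877 and 668 with a mean of at least 10 reads. Higher genes were 314 to 371 with 1 library left out, and lower genes were 335 with no filter and 285 to 381 with 1 library left out. Of the main calls, 968 were shared with voom on the same genes, all in the same direction. Genes changed at least 2-fold numbered 1 in the main test, 0 with a mean of at least 5 FPKM, which removes Slc24a4, 6 with a pseudocount of 0.1, 11 or 45 with voom and 1 to 2 with 1 library left out. The test against a 1.5-fold threshold called 4, of which only Slc24a4 was fitted at 2-fold or more. The replicate block gave 825 calls, and the deviations of same-numbered libraries had correlations of -0.0024, 0.055 and -0.021, so the numbers only name the libraries. The alternatives meant for a table of counts were not run.

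Lists past the threshold were 8 in the main test, 1 with an estimated correlation, 5 with a mean of at least 5 FPKM and 6 to 10 with 1 library left out. With an estimated correlation the adjusted p was 0.0733 for the ER chaperone, mitotic and lysosome lists, 0.116 for DNA replication, 0.214 for pyroptosis, 0.490 for immediate early genes and 0.766 for ribosomal proteins. The estimate itself was 0.0104 for the lysosome list, near the preset 0.01, and -0.056 for pyroptosis. A higher correlation between genes thus does not account for the weaker adjusted p of these lists. The estimated form of camera also uses the few residual degrees of freedom of the 6 libraries, which by itself raises its p-values. For the others that lost the threshold the estimate was 0.055 to 0.502. There both the correlation and the degrees of freedom enter, in shares that were not tested. Pyroptosis was at 0.0914 with no filter and 0.0518 with a mean of at least 5 FPKM, which gave 0.485 for immediate early genes and 0.0526 for ribosomal proteins. Ribosomal proteins were at 0.537 with quantile normalization. ATF4 and CHOP targets passed with no filter (0.0494) and with voom (0.0295). With 1 library left out the range was 0.0108 to 0.298 for ATF4 and CHOP targets, 0.00922 to 0.110 for immediate early genes and 0.000130 to 0.782 for ribosomal proteins. The cause of the changes under the other settings was not tested.

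No gene or list whose sign turned passed limma or camera in the main test, though some of these lists passed fry. Cdkn1a was at -0.010 and Pecam1 at 0.0036 with quantile normalization. With voom Mdm2 was at 0.0014, or 0.0046 with a mean of at least 10 reads. With 1 library left out the ranges were -0.022 to 0.024 for Cdkn1a, -0.077 to 0.027 for Pecam1 and -0.027 to 0.0062 for Mdm2. List directions turned, with the adjusted p given, for the BCL2 family (0.852) and mitochondrially encoded genes (0.895) with a mean of at least 5 FPKM, interferon (0.813), immune markers (0.813) and fibroblast markers (0.678) with no filter, interferon with voom (0.848) and hypoxia and glycolysis with quantile normalization (0.742). With 1 library left out the adjusted p ranged over 0.251 to 0.972 for heat shock, 0.842 to 0.981 for interferon, 0.144 to 0.998 for hypoxia and glycolysis and 0.360 to 0.970 for mitochondrially encoded genes. Depth limits low genes most: Gsdmd had 46 to 85 reads per library.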

Other observations

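In this part the tests of whole-sample splits for the total count of changed genes and of the spread of the p53 targets were chosen after their results were seen. The 6 libraries can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. The real division gave 1060 changed genes, 498 higher, 562 lower and 1 changed at least 2-fold, and the highest of the other divisions gave 0 for each. In each of these counts the real division was the only 1 of 10 as large. The other divisions mix both treatments on each side, so a difference between treatments widens the spread within the sides. Few calls were likely there for that reason, and the contrast does not show what chance alone would give. Those 9 divisions had between 243 and 449 genes with an unadjusted p under 0.05 in limma, against 2803 in the real one, and voom called 0 in them. For gene lists at the preset correlation, 4 of the 10 divisions gave as many as the real one, with 8 lists in the real division and 8 in the highest of the others. A real difference stays in part in the other divisions, since their sides hold unequal numbers of rPPAA18C6@Dox libraries. In the other divisions the melanocyte and ER lists passed in all 9, the mitotic list in 7 and the replication list in 6. Their smallest adjusted p there were 7.27e-06, 0.000322, 0.000208 and 0.000233, against 1.05e-23, 1.89e-15, 3.30e-10 and 3.18e-09 in the real one. Some other lists had a smaller camera adjusted p in another division than in the real one. It was 1.73e-05 against 0.0413 for ribosomal proteins, 1.47e-08 against 0.807 for hypoxia and glycolysis, and 0.000273 against 0.0536 for ATF4 and CHOP targets. With an estimated correlation no list passed in the other divisions, where a difference between treatments also enters the spread that sets that correlation. A pass was unlikely there for that reason, so this does not set the melanocyte list apart.

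The rise of the melanocyte list is the clearest group pattern. Gene length and GC content do not account for it: with the trend of fold change on expression, length and GC removed, the median of the 20 members was 0.22, against 0.24 before, and the central 95% of 10000 random lists of the same size reached up to 0.035. Raised cAMP and CREB signalling may be behind it, as Ppargc1a and Fos are known CREB targets, but 8 tested CREB targets picked without sight of their values gave a camera p of 0.248. Lower ERK output could be another route, since Dusp6 fell, but Dusp4 and Fos rose, and of 10 ERK output genes picked in the same way (median 0.021, p of 0.576) only Spred1 fell and none rose. Both ideas came from these data and both lists left out genes already known to lead the changes, so both stay open, as does a direct effect of the preparation on melanocyte genes.

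Targets of p53 did not rise as a list, a pattern of interest if Dox in the code name stands for doxorubicin, which the labels do not spell out. A spread too wide to show a 1.5-fold rise is argued against, since 100% of the 27 tested targets had an upper 95% limit under a 1.5-fold rise, and 26 had one under 1.2-fold. Only 4 genes of any kind passed the test against 1.5-fold here, so these limits leave smaller rises of some targets open. Too little drug at the DNA by 8 h, or a weak response of this line, stays open as untested.

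Malat1 and ND6 fell by similar amounts and were both highest in PBS replicate 1, which invites a technical explanation. A lower share of mitochondrial RNA is argued against, because the 12 other mitochondrial genes had a median log2 fold change of 0.012. A lower yield of long noncoding RNA may contribute: the median of the 364 tested lncRNA genes was -0.037, just below the central 95% of protein-coding lists matched on expression (-0.033 to -0.011), but far smaller than the change of Malat1 (-0.54). Less carry-over of RNA without a poly(A) tail could lower both, and the 5 tested replication-dependent histone genes had a median of -0.14 with members from -0.20 to 0.02, too few and too variable to decide. A response to the treatment stays open beside it.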
